A study of Mus musculus with 6 samples.

How the data were processed

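DNA of formalin-fixed small intestine samples was enriched for exons and sequenced as paired reads of 75 bp, per the labels' protocols. Files of 5 tumor samples were used, and the adjacent normal entered through the normal column of each tumor's file. The deposited files are lists of somatic SNVs made by the authors with Strelka 2.0.17 on the GRCm38 build, per the file headers. Each list compares a tumor with a normal, and all 493 calls carry the PASS filter, have the normal typed as reference and a joint somatic quality of at least 15. GATK, FastQC and the mm10 build are also named in the submitters' processing notes, with no role given. The aligner, the duplicate removal and the capture regions are not given in the sources used here. The column headed normal was taken as the only sample labelled normal. At all 29 SNVs listed in more than 1 tumor, the lists give identical normal read counts, so the same normal library was subtracted from every tumor.

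The deposited values are raw read counts per base at each called site for tumor and normal, per the file headers, in 2 tiers of mapping stringency, and they are not normalized. The quality is the caller's Phred-scaled score for a somatic difference, per the file headers. Gene names, consequences, codons, SIFT classes and known-variant identifiers are the authors' annotation with VEP release 90 (GENCODE M15, GRCm38.p5, dbSNP 146), per the file headers. A somatic list depends on the depth of both libraries, on the caller's thresholds and on the choice of normal. Changes below these thresholds, and sites with too few reads, are missing from it.

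From these files, the variant share of a call was computed as tier 1 reads with the variant base over tier 1 reads with the reference or variant base. Each SNV received its most severe consequence over transcripts. Missense, stop-gained, stop-lost, start-lost and splice donor or acceptor changes counted as protein-altering. Substitutions were written from the pyrimidine of the base pair, which gives 6 classes. Bases next to a changed base came from the annotated codon, so they were known for coding SNVs only and only within the codon. Gene coordinates and the number of protein-coding genes (21900) came from a RefSeq table of GRCm38.p6, which has the same primary assembly as the files. All 161 genes of the pathway lists were found there, as were 227 of the 243 genes with a protein-altering SNV. All 55 named calls with a gene location lay inside that gene's span.

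Counts per tumor carry exact Poisson 95% intervals, and shares carry Wilson intervals unless another method is named. Where a count was 0, the upper limit is 3 reads over the depth. Equal counts were tested by a Monte Carlo exact multinomial test, pairs of tumors in a mouse by exact binomial tests, and mouse 3 against mice 1 and 2 and the sharing of SNVs by exact two-sided permutation. Spectra were tested by 100000 permutations of calls over tumors. Gene lists were tested by exact two-sided binomial tests, and recurrence of genes by 10000 random placements. Families of tests were adjusted by the Benjamini-Hochberg method. The tumors were grouped and numbered by mouse and tumor as labelled. The labels give no sequencing batch, so no within-batch value could be had.

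The gene lists, comparisons, tests and most alternatives were fixed before the data were examined. They comprise 8 pathway lists (Wnt, RAS and receptor kinases, TGF-beta and BMP, PI3K, p53 and cell cycle, DNA repair, chromatin, Notch and differentiation), a list of very long genes, and families of olfactory and vomeronasal receptors, zinc fingers and other multi-copy genes. Genes were named by a rule fixed at the same time: Kras, Apc, Ctnnb1 and Trp53; pathway genes with a protein-altering SNV (at most 30); genes hit in at least 2 tumors (at most 15); and genes with a stop-gained, start-lost or splice-site SNV (at most 10). The rule named 35 genes.

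The plan deviated in these points. Placement in proportion to coding length and a neutral expectation for the protein-altering ratio need a genome sequence or coding lengths, which were not used here. Equal chance per protein-coding gene replaced coding length, with gene span as an added alternative. The split of calls into T>G and other classes, the comparison of depth ratios and the quality threshold of 30 were added after the spectrum was seen. Other alternatives left out known variants, shared SNVs, clustered SNVs (within 100 bp), multi-copy families, C>T changes or each tumor in turn, used the canonical transcript, or required 10% of reads and a depth of 20. No per-sample column of the files remained unused (0).

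The tests were tested on simulated data before use. With no difference planted, the spectrum test called 6.5% of 200 simulated sets of 493 SNVs, and it called 100% when 40% of the SNVs of 1 tumor were moved to C>A. The gene list test called a list in 1.5% of 200 sets of 269 randomly placed SNVs, and called the Wnt list in 100% when 6 SNVs were placed in it. These SNVs were placed with equal chance per gene, as the test assumes, so unequal gene length was not simulated. The test of equal numbers called 3.5% of 200 sets. The sharing test gave its smallest possible p, 0.0667, with 30 planted SNVs shared within mice. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.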

Results

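Whole-exome sequencing was used to list somatic single-nucleotide variants (SNVs) in tumors of the mouse small intestine. The labels give every sample the Kras Q61R genotype, in which the small GTPase Kras carries an activating change at codon 61. The series held 5 tumors from 3 mice (1 tumor of mouse 1, 2 of mouse 2 and 2 of mouse 3) and 1 adjacent normal tissue sample, which carries the same animal label as the mouse 3 tumors. The 5 lists held 493 calls at 456 distinct SNVs, all called against the normal. At the called sites the median tumor depth was 87 reads in mouse 1 tumor 1, 75 and 92 in tumors 1 and 2 of mouse 2, and 134.5 and 112 in tumors 1 and 2 of mouse 3, with a range of 12 to 2152. Intervals below are 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Each tumor was sequenced as 1 library, and the 5 tumors are the replicates of 1 group.

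The first comparison asked which genes of intestinal tumor pathways had acquired an SNV in addition to the Kras allele. Ctnnb1, which encodes beta-catenin, the effector of canonical Wnt signaling, carried the same missense SNV in mouse 1 tumor 1 (joint quality 32) and mouse 2 tumor 1 (joint quality 27), so that a joint quality of at least 30 would keep only the call of mouse 1. The change, S37F, replaced a serine in the N-terminal stretch whose phosphorylation marks beta-catenin for degradation. It lay at position 120950618 of chromosome 9 (GRCm38) in exon 3 of 15, within a gene spanning 120933400 to 120960507, and the annotation gave it a deleterious SIFT prediction. The variant base was on 10 of 42 reads in mouse 1 tumor 1 (23.8%, Wilson interval 13.5 to 38.5%) and on 8 of 37 reads in mouse 2 tumor 1 (21.6%, 11.4 to 37.2%). The adjacent normal had 0 of 33 reads, which allows a share of up to 9.09%. No SNV was listed in Apc, the scaffold of the beta-catenin destruction complex, in the tumor suppressor Trp53, or in Kras itself. The normal has the Kras genotype too and was typed as reference at every listed site, so a list made against it does not show the engineered allele. The lists give no reads at uncalled positions, so the depth at these genes in the remaining tumors is unknown, and small insertions or deletions were not analysed here.

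Beyond Ctnnb1, 7 of the 161 genes in 8 pathway lists carried a protein-altering SNV, each in 1 tumor. Among chromatin regulators, the histone methyltransferase gene Kmt2a had D2668N in mouse 1 tumor 1, on 25 of 81 reads (30.9%, Wilson interval 21.9 to 41.6%). Its relative Kmt2d had A1503D in mouse 3 tumor 2 (14.5% of reads, 7.56 to 26.2%), and the acetyltransferase gene Crebbp had L212R in mouse 2 tumor 2 (10.7%, 5.74 to 19.1%). In the growth factor to PI3K group, the receptor gene Igf1r had G468R (9.76%, 5.03 to 18.1%) and the kinase gene Akt3 had V162G (19.4%, 9.19 to 36.3%), both in mouse 3 tumor 2. Notch1, a receptor that directs intestinal cell fate, had C1218W in mouse 1 tumor 1 (23.7%, 12.99 to 39.2%), and Cic, a repressor downstream of MAPK signaling, had K1373Q in the same tumor (16.0%, 10.5 to 23.6%). The adjacent normal had no variant read at these 7 sites, among 15 reads for Akt3, which allows a share of up to 20%, to 237 reads for Cic. The joint quality was 15 for Akt3, the lowest value in any list, and 17 for Crebbp. For the others it ran from 30 (Notch1) to 140 (Kmt2a). None of the 15 TGF-beta and BMP genes, the 16 p53 and cell cycle genes or the 20 DNA repair genes had an SNV in any list. These lists are short and leave out other genes of the pathways. Mouse 1 tumor 1 had missense SNVs in the DNA ligase gene Lig4 (R802C, 38.9% of reads) and the cyclin gene Ccnb1 (T71I, 45.7%). It also had them in the frizzled receptor gene Fzd10 (D379E, 11.1%) and the receptor kinase gene Ret (K822T, 13.5%). These examples lie outside the lists and were named after their values were seen. The Wilson intervals of Lig4 (27.0 to 52.2%) and Ccnb1 (38.0 to 53.6%) include 50%. The normal carries the animal label of mouse 3, so inherited variants of mouse 1 cannot be told apart from acquired ones at these 2 sites. The SNVs of Crebbp, Akt3, Notch1 and Cic were T>G changes, a class treated separately in the comparison of substitution types. Those of Kmt2a and Igf1r, like that of Ctnnb1, were C>T changes, a class that fixed tissue can add.

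Chromatin regulators held 3 protein-altering SNVs against 0.221 expected if the 269 calls fell on all 21900 protein-coding genes with equal chance (exact binomial test, adjusted p = 0.0182 over 12 lists). The list of very long genes also held 3, in the cytolinker gene Dst, the protocadherin gene Fat4 and the receptor gene Lrp1b, against 0.368 expected (exact adjusted p = 0.0377). That chance ignores gene length. With chance in proportion to gene span, the exact adjusted p was 0.0526 for chromatin regulators and 1 for long genes, while olfactory and vomeronasal receptors (25 against 1.48 expected, 1.23e-21) and other multi-copy families (33 against 12.2, 1.78e-06) passed. Gene span includes introns, which exon capture leaves aside, so it does not stand for coding length. It cut the number expected in receptor genes from 17.99 with equal chance to 1.48. These span values are therefore no measure of enrichment in either direction. No other list passed with equal chance and all calls. The Wnt list of 25 genes, which lacks Fzd10, held 2 calls, both the Ctnnb1 SNV, against 0.307 expected (exact adjusted p = 0.115), and the PI3K list 2 against 0.197 (adjusted p = 0.0676). The RAS and receptor kinase list held 1 (exact adjusted p = 0.525) and the Notch and differentiation list 1 (adjusted p = 0.416). The p53, TGF-beta and repair lists held 0 (exact adjusted p = 1 for each). Olfactory and vomeronasal receptor genes held 25 calls against 17.99 expected (exact adjusted p = 0.211), zinc finger genes 3 against 5.79 (adjusted p = 0.525), and other multi-copy families 33 against 28.3 (adjusted p = 0.525). These calls depended on which SNVs and tumors entered. Without T>G calls the Wnt list (2 against 0.103 expected, exact adjusted p = 0.0195), the chromatin list (2 against 0.0740, 0.0155) and the receptor list (16 against 6.02, 0.00354) passed, and the long genes did not (0.279). At a joint quality of at least 30 the chromatin list (exact adjusted p = 0.0276), the receptor list (22 against 8.09, 0.000202) and other multi-copy families (22 against 12.7, 0.0430) passed. Without mouse 1 tumor 1 the exact adjusted p was 0.0787 for the chromatin list and 0.135 for long genes, and without mouse 3 tumor 2 it was 0.109 for both. Without mouse 2 tumor 1 it was 0.187 for long genes. The receptor list passed without mouse 2 tumor 2 (exact adjusted p = 0.0170), and the PI3K list without mouse 2 tumor 2 (0.0369) or mouse 3 tumor 1 (0.0499).

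The next comparison concerned the number of SNVs per tumor. Mouse 3 tumor 2 had the most, 149 SNVs (exact Poisson interval 126 to 175), followed by mouse 2 tumor 2 with 118 (97.7 to 141), mouse 1 tumor 1 with 105 (85.9 to 127), mouse 3 tumor 1 with 74 (58.1 to 92.9) and mouse 2 tumor 1 with 47 (34.5 to 62.5). The mean was 98.6 ± 39.5 SNVs (SD, n = 5), of which 53.8 ± 24.8 altered a protein. Equal numbers in the 5 tumors were excluded by a Monte Carlo exact multinomial test (p = 1e-05, the smallest that 100000 draws can give). Within mice, tumor 2 had more SNVs than tumor 1 both in mouse 2 (118 against 47, exact binomial adjusted p = 6.26e-08) and in mouse 3 (149 against 74, adjusted p = 5.71e-07), a test of counting error that compares libraries. Among SNVs other than T>G, a subset chosen after the substitution types were seen, mouse 2 tumor 2 had fewer than tumor 1 (12 against 38, exact binomial adjusted p = 0.000612). The mouse 3 tumors had 59 and 44 such SNVs (exact adjusted p = 0.167). At a joint quality of at least 30, also chosen afterwards, tumor 2 had 1 SNV more than tumor 1 in mouse 2 (exact binomial p = 1) and 22 more in mouse 3 (p = 0.0467). Unlike the values above, these p-values were not adjusted over the mice, so 0.0467 does not show that the mouse 3 difference passes.

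**Figure D1:**
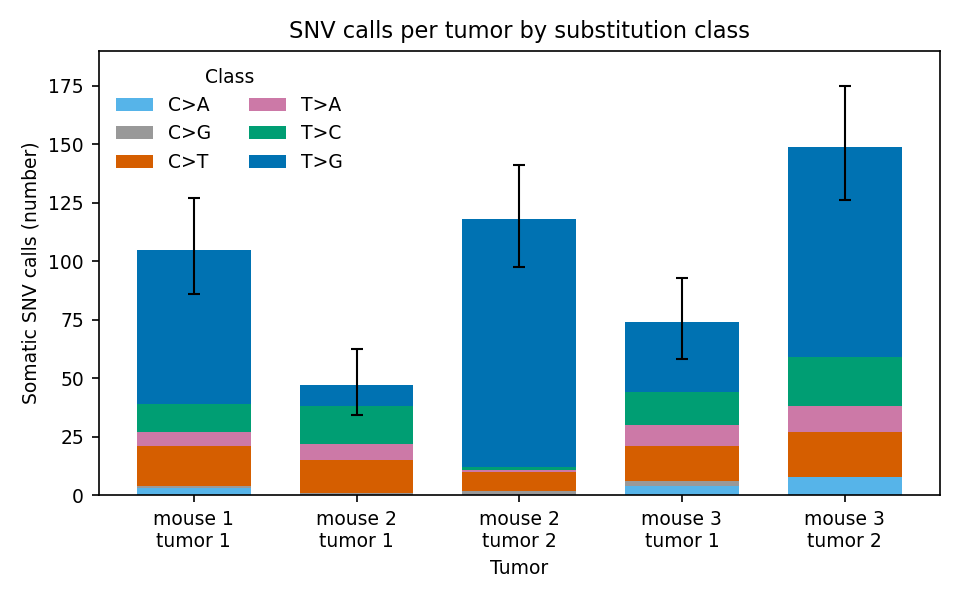
Stacked bars give the number of somatic SNV calls (vertical axis) in each of the 5 tumors (horizontal axis), colored by the 6 substitution classes, with the exact Poisson 95% interval of the total as error bar. T>G calls range from 9 in mouse 2 tumor 1 to 106 in mouse 2 tumor 2, while the other classes together range from 12 to 59.

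Substitution types were compared next, because fixed tissue can add C>T changes and mutational processes differ in type. T>G changes (A>C on the other strand) were the most frequent class, with 301 of 493 calls, and their share ran from 19.1% (Wilson interval 10.4 to 32.5%) in mouse 2 tumor 1 to 89.8% (83.1 to 94.1%) in mouse 2 tumor 2. The mean T>G share was 54.6 ± 26.4% (SD, n = 5). C>T changes, the class raised by cytosine deamination, made up 17.2 ± 8.62% and T>C changes 15.9 ± 12.1% (SD, n = 5). T>A changes made up 8.20 ± 5.51%, C>A 2.73 ± 2.69% and C>G 1.496 ± 1.05% (SD, n = 5). The spectrum differed between tumors (chi-square 107, permutation p = 1e-05, the smallest that 100000 permutations can give). Without T>G calls the remaining 5 classes did not pass the same test (chi-square 23.6, permutation p = 0.0945). T>G calls lay at sites of lower relative tumor depth: the median ratio of tumor to normal depth was 0.560 at T>G sites against 1.21 at other sites in mouse 1 tumor 1, 0.552 against 0.975 in mouse 2 tumor 2, and 0.730 against 1.22 in mouse 3 tumor 2. The difference in log2 ratio passed a permutation test in these 3 tumors (adjusted p = 3.33e-05 in each), and not in mouse 2 tumor 1 (adjusted p = 0.161) or mouse 3 tumor 1 (adjusted p = 0.635).

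Protein-altering changes were set against synonymous ones. Missense and stop-gained SNVs numbered 266 and synonymous SNVs 56, a ratio of 4.75, or 82.6% protein-altering (exact binomial interval 78.0 to 86.6%). The ratio per tumor was 4.83 ± 1.36 (SD, n = 5), from 3.17 in mouse 2 tumor 1 to 6.56 in mouse 1 tumor 1. It was 5.5 among T>G calls and 3.75 among the other classes, a difference that did not pass Fisher's exact test (p = 0.22). A ratio expected without selection was not computed, because no genome sequence was used here.

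A stop-gained or start-lost SNV was found in 10 genes, each in 1 tumor. In mouse 1 tumor 1 these were Gtf3c1 (Y2075*), a subunit of the RNA polymerase III factor TFIIIC, the vomeronasal receptor gene Vmn2r100 (R835*), and the glutamate receptor gene Gria3 (start lost, M1R). The Gria3 change was a missense change in the canonical transcript, whereas the other 9 kept their consequence there. Mouse 2 tumor 1 had a stop in the cathepsin gene Cts6 (R306*). Mouse 2 tumor 2 had stops in the lipid transfer protein gene Vps13d (Y1245*) and the focal adhesion gene Tns3 (Y333*) and a lost start in the transferrin gene Trf (M1R). Mouse 3 tumor 1 had a stop in the vomeronasal receptor gene Vmn2r6 (W133*), on 63 of 329 reads (19.1%, Wilson interval 15.3 to 23.7%). Mouse 3 tumor 2 had stops in the otoferlin gene Otof (Y473*) and the protocadherin gene Pcdhb12 (Y513*). Those of Vmn2r6, Vmn2r100 and Cts6 were C>T or T>A changes, and the remaining 7 were T>G changes. The joint quality was 164 for Vmn2r6 and 43 for Cts6. For the others it ran from 15 (Gria3 and Trf), the lowest value in any list, to 23 (Tns3).

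The sharing of identical SNVs asked whether tumors of the same mouse had more in common than tumors of different mice. A total of 29 distinct SNVs were listed in more than 1 tumor, 23 of them in tumors of different mice. Missense SNVs in Sulf1 (D640N), an extracellular heparan sulfate sulfatase, in Ube4a (N602Y), a ubiquitin ligase, and in Qrsl1 (A439T), a subunit of a mitochondrial amidotransferase, were listed in all 3 tumors of mice 1 and 2 and in no tumor of mouse 3. So were a synonymous SNV in Ssc5d and an SNV downstream of the predicted gene Gm6089. The Sulf1 variant was on 98.1 to 100% of reads and the Qrsl1 variant on 51.9 to 63.3%. The Ube4a variant was on 50.6% of reads in mouse 1 tumor 1 (Wilson interval 39.95 to 61.2%) and on 98.7% (92.8 to 99.8%) and 100% (95.4 to 100%) in the mouse 2 tumors. The adjacent normal had no variant read at these 5 sites among 22 to 72 reads. Nfkb1, a subunit of the inflammatory transcription factor NF-kappa-B, had V527M in both mouse 2 tumors only, on 54 of 158 pooled reads (34.2%, 27.2 to 41.9%) and on 0 of 185 reads of the normal, which allows up to 1.62%.

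The mean Jaccard index of identical SNVs was 3.36% for the same-mouse pairs and 2.11% for pairs from different mice, a difference of 1.25 percentage points that did not pass an exact two-sided permutation test of the mouse labels (p = 0.733, with 0.0667 the smallest that 15 labelings allow). Without T>G calls the indices were 10.7% and 3.20% (exact permutation p = 0.0667, the smallest possible), so this design could not reach 0.05. Sharing did not follow the mouse alone. The index was 16.3% for the mouse 2 pair and 5.10% for the mouse 3 pair. Mouse 1 tumor 1 reached 10% and 13.3% with tumors 1 and 2 of mouse 2. With all classes, the difference was 0.0311 percentage points without multi-copy families and 0.251 without known variants. All 14 shared T>G SNVs were shared between different mice, and 11 of them joined mouse 1 tumor 1 and mouse 2 tumor 2. SNVs on 40% or more of reads numbered 11 in mouse 1 tumor 1, 6 and 4 in tumors 1 and 2 of mouse 2, and 1 and 0 in tumors 1 and 2 of mouse 3 (exact permutation p = 0.2 for mouse 3 against mice 1 and 2, the smallest possible).

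**Figure D2:**
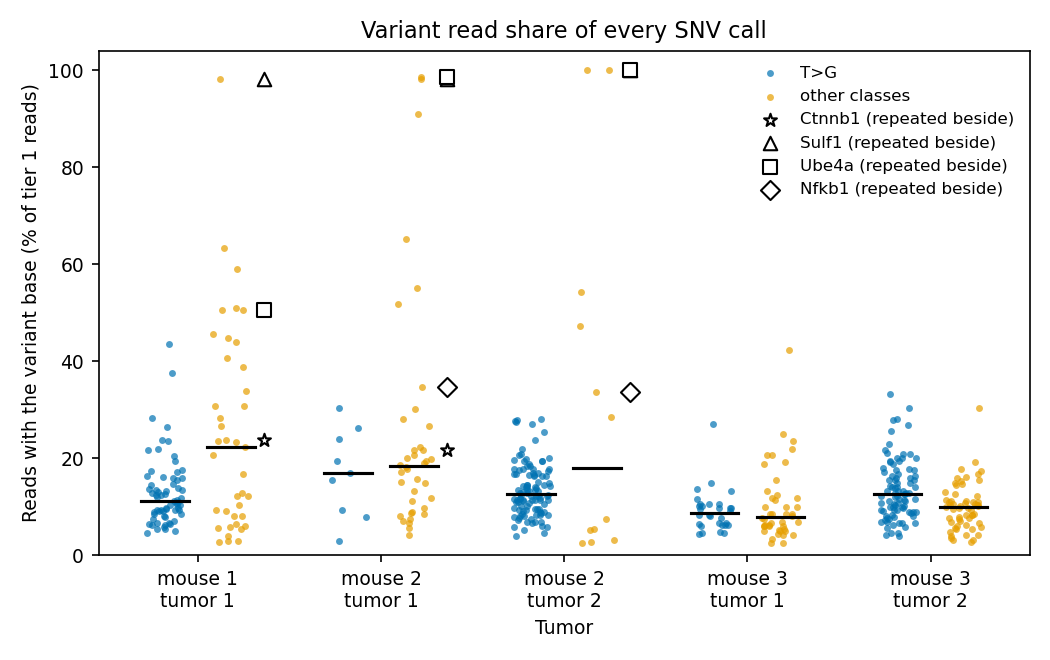
Each point is 1 SNV call, with the percent of tier 1 reads carrying the variant base on the vertical axis and the 5 tumors on the horizontal axis; T>G calls are blue, other classes orange, black lines are medians, and open symbols repeat the Ctnnb1, Sulf1, Ube4a and Nfkb1 SNVs beside their column. Points at 40% or above number 11, 6 and 4 in the tumors of mice 1 and 2, and 1 and 0 in the mouse 3 tumors.

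**Figure D3:**
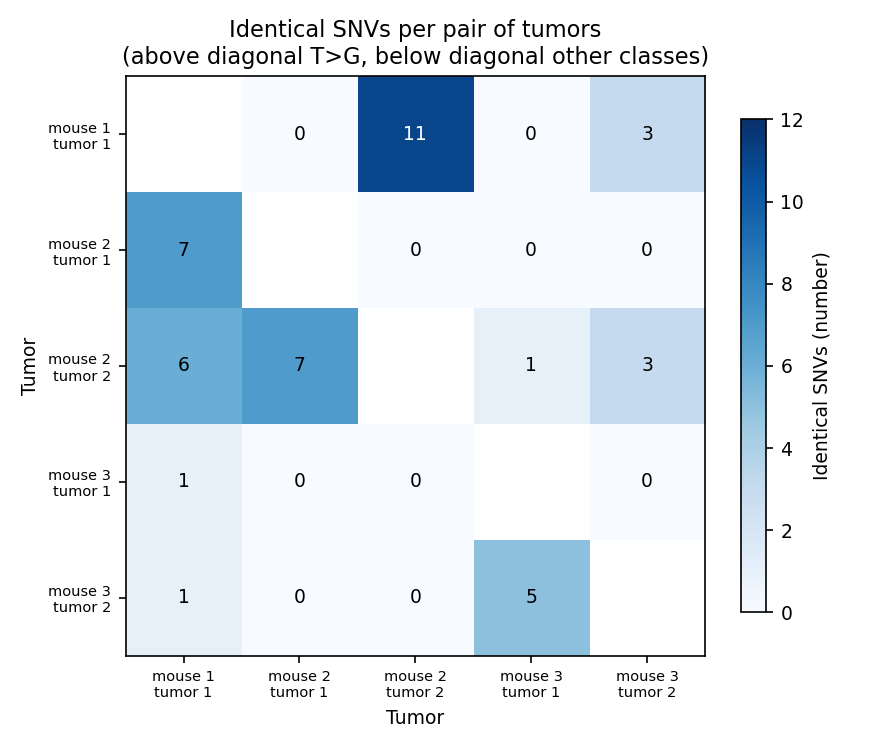
Each cell gives the number of identical SNVs in a pair of tumors (rows and columns are the 5 tumors), with T>G calls above the diagonal and the other classes below, and darker blue for more. The highest T>G number is 11 for mouse 1 tumor 1 with mouse 2 tumor 2, and the highest number of other classes is 7, for mouse 2 tumor 1 with mouse 1 tumor 1 and with mouse 2 tumor 2.

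Recurrence was then examined at the level of genes. Protein-altering SNVs hit 16 genes in at least 2 tumors, against a median of 1 and an upper bound of 4 in the central 95% of random placements with equal chance per gene (one-sided permutation p = 1e-04, the smallest that 10000 random placements can give). The excess over the median was 15 with equal chance and 9 with chance in proportion to gene span (one-sided permutation p = 0.00599, with fewer placements). Gene span includes introns, which exon capture leaves aside. The span value therefore does not show that the excess holds after allowing for coding length. In 14 of them the tumors carried an identical SNV. Besides Ctnnb1, Sulf1, Ube4a, Qrsl1 and Nfkb1, these included Eif4a3, the RNA helicase of the exon junction complex (H223Q, T>G), and the class I histocompatibility gene H2-Q1 (Q217P, T>G), each in mouse 1 tumor 1, mouse 2 tumor 2 and mouse 3 tumor 2. The Eif4a3 change was on 76 of 377 pooled reads (20.2%, Wilson interval 16.4 to 24.5%) and on 0 of 168 normal reads. T>G SNVs in Pkm (D281E), encoding pyruvate kinase, the acetylcholine receptor gene Chrng (S176R), Fign (N474K), the inner ear gene Otog (S434R), the protocadherin gene Pcdhb16 (S686R) and the GTPase-activating protein gene Sipa1, which lies outside the naming rule and was added after its values were seen, each recurred in 2 tumors. Duxf3, a multi-copy homeobox gene, was hit in 4 tumors by P260T or R241H, each on 2.51 to 3.03% of reads, and the normal carried both variants on 24 of 1374 and 25 of 1415 reads.

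When identical SNVs were left out, 2 genes remained: the focal adhesion protein gene Tln1 (M113L and Y373D, in the 2 mouse 3 tumors) and Mroh2a (V519G in mouse 2 tumor 2 and N168H in mouse 3 tumor 2). All 4 were T>G changes, and 2 genes did not exceed chance (one-sided permutation p = 0.25 by 10000 random placements).

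The last comparisons used the animal of the normal, since calls in mice 1 and 2 can include inherited differences between animals. The mouse 3 tumors had a mean of 111.5 SNVs and the tumors of mice 1 and 2 a mean of 90, a difference of 21.5 that did not pass an exact two-sided permutation test (p = 0.8, with 0.2 the smallest that 10 splits allow). Without mouse 3 tumor 2 the difference was -16, and at calls on at least 10% of reads with a depth of at least 20 it was -1.83. Without T>G calls the means were 51.5 in mouse 3 and 29.7 in mice 1 and 2. That difference of 21.8 had an exact permutation p = 0.2, the smallest possible. SNVs with an identifier of a known mouse variant made up 3.64 ± 3.54% (SD, n = 5) of each list, 6.07% on average in mouse 3 and 2.02% in mice 1 and 2 (exact permutation p = 0.4, with 0.2 the smallest possible). The tumors of mouse 3 had 9.46% and 2.68%, and without mouse 3 tumor 1 the mean over the remaining tumors was 2.18%.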

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

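The tests of a neighboring G, of a neighboring T and of the joint quality at T>G calls were planned before their results were seen. The interval in the joint quality test, the comparison with unchanged T bases and the exclusion of sites followed by C were not part of the planned rules. The other tests of explanations in this part were chosen afterwards. No tumor stood apart from the other 4 in any of 22 measures by Dixon's test. Outside the T>G class, mouse 2 tumor 2 came close, with gaps of 0.707 (depth ratio) and 0.706 (joint quality) of the range. The critical value was 0.71.

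The adjacent normal, which enters the lists only as a control, carried more than 3 variant reads at 10 distinct SNVs. They were 2 in Duxf3 (25 and 24 reads, 1.77 and 1.75% of the normal's reads), and 1 each in AW822073 (19 reads), Wrb (14), Ndfip2 (11), AC149090.1 (11), Vmn2r-ps159 (7), H2-D1 (6), an unnamed position of an unplaced scaffold (6) and Anks1 (4). At the Duxf3 sites the tumors carried the variants on 2.51 to 3.03% of reads. At Ndfip2 the share was 3.97% in the normal and 25.7% in the tumor.

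T>G calls exceeded all other classes together in mouse 1 tumor 1, mouse 2 tumor 2 and mouse 3 tumor 2. At the 14 T>G sites listed identically in different mice, among them Eif4a3, H2-Q1 and Pkm, separate somatic events at random T positions are argued against, while a site-specific error or a mutation hotspot stays open there. A base-calling error that depends on the following base cannot be told apart. Its planned rule, an odds ratio interval above 1 on at least 1 side, was met on the following side only. For G before the changed T, T>G sites did not differ from T>C and T>A sites (odds ratio 1.23, 95% interval 0.453 to 3.92, Fisher's exact adjusted p = 0.817). G followed the changed T more often at T>G than at T>C and T>A sites (odds ratio 3.39, 95% interval 1.19 to 11.2, Fisher's exact adjusted p = 0.0338 over both sides). It followed 42.3% of T>G sites and 26.8% of unchanged T bases in the listed codons, which were not matched by codon position (odds ratio 2.0, 1.07 to 3.74, exact adjusted p = 0.0539). With sites followed by C left out, G followed 49.4% of unchanged T bases, 45.2% of T>G sites (odds ratio 0.848, 0.424 to 1.69) and 21.4% of T>C and T>A sites (odds ratio 0.283, 0.0844 to 0.823, exact adjusted p = 0.0180), so few G at the comparison sites may account for part of the first odds ratio. An intestinal process that places T>G before a T stays open too, with T following at 47.4% of sites (36.7 to 58.4%) around the preset limit of 50%. For calls close to the caller's threshold, the T>G share was 44.3% (37.8 to 51.1%) at a joint quality of 30 or more against 78.3% below. The share of 44.3% exceeded the preset limit of 39.1%, so the planned rule, which used no interval, went against this cause. That limit lay inside the interval, however, so the cause stays open here.

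The same Ctnnb1 S37F SNV appeared in tumors of 2 mice. Carry-over of DNA between these libraries was tested on the other SNVs at or above the Ctnnb1 share and outside the T>G class: of 16 in mouse 1 tumor 1, 4 were listed in mouse 2 tumor 1 (Wilson upper limit 49.5%), and of 12 in mouse 2 tumor 1, 5 were listed in mouse 1 tumor 1 (upper limit 68.0%). All of these shared SNVs were also listed in mouse 2 tumor 2 and may be inherited. With the SNVs of that tumor left out, 0 of 12 (upper limit 24.2%) and 0 of 6 (39.0%) were listed, which argues against carry-over in both directions at a limit of 50%, but into mouse 1 tumor 1 only with this exclusion. A heterozygous inherited variant is argued against by the pooled share of 22.8% (14.9 to 33.2%), and separate acquisition of the change in part of the cells of both tumors stays open as a hypothesis. The SNV is a C>T change, a class that fixed tissue can add. Fixation damage and a site-specific error were not tested for it.

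SNVs near 50% or 100% of reads were concentrated in mice 1 and 2: the lowest number at 40% or more was 4 there and the highest in mouse 3 was 1. This may reflect variants that mice 1 and 2 inherited and the animal of the normal did not, since the only normal carries the animal label of mouse 3. Identifiers of known variants give this no backing. The SNVs of Sulf1, Ube4a, Qrsl1 and Ssc5d had no such identifier. The share of calls with one was 6.07% in mouse 3 and 2.02% in mice 1 and 2, a difference that did not pass an exact permutation test (p = 0.4). A heterozygous normal would show as few variant reads with a chance of at most 0.000122 at each of 13 sites. Every listed call has the normal typed as reference, so this outcome was largely set by the calling rule. It is no independent test of whether the normal had too few reads. Sulf1, Ube4a, Qrsl1 and Ssc5d were listed in both mouse 2 tumors, but Ing1 (90.9% of reads) and Klhl5 (65.2%) only in mouse 2 tumor 1, which inheritance alone does not account for unless the calls were missed in tumor 2, where the depth at these sites is unknown. Loss of the other allele in these tumors stays open as well, and was not tested.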

How the results depend on the processing

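The alternatives without T>G calls, with a joint quality of at least 30, and with chance by gene span were chosen after the data were seen. Of 151 recomputed values, 126 kept their direction and side of the threshold, stayed within the spread or, for counts, within 1.5-fold. Another 17 moved, 4 reversed and 4 lost significance. The p-values of differences within a mouse were not adjusted over the mice in this part, so a kept value near 0.05 may not pass after adjustment. The tests of mouse 3 against mice 1 and 2 and of sharing could not reach 0.05 in any setting. The 10 values that each of them kept therefore say nothing about significance.

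Without T>G calls there were 38.4 SNVs and 18 protein-altering SNVs per tumor, a C>T share of 42.7%, 6 genes hit in 2 or more tumors, a spectrum chi-square of 23.6 (permutation p = 0.089 with fewer draws), and a tumor 2 minus tumor 1 difference of -26 SNVs in mouse 2 (reversed, exact p = 0.000306) and 15 in mouse 3 (exact p = 0.167). With a joint quality of at least 30 there were 46 SNVs and 24.2 protein-altering SNVs per tumor and 7 genes hit, and the mouse 2 difference was 1 (exact p = 1) and the mouse 3 difference 22 (exact p = 0.0467). On at least 10% of reads at a depth of at least 20 there were 58.6 SNVs per tumor, 8 genes hit, 1 gene list, and a mouse 3 difference of -1.83 (reversed). Without SNVs listed in more than 1 tumor, 2 genes were hit, an excess of 1 over chance (permutation p = 0.259 with fewer placements). The other genes recur through identical SNVs, which this setting removes. For the other changes, beyond the removal of calls itself, the cause was not tested.

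Leaving out each tumor in turn, the genes hit ranged from 9 (without mouse 2 tumor 2) to 15, with 10 without mouse 1 tumor 1. The gene lists passing ranged from 0 (without mouse 1 tumor 1, or without mouse 3 tumor 2) to 4 (without mouse 2 tumor 2), with 1 without mouse 2 tumor 1. The sharing difference ranged from -0.121 (without mouse 2 tumor 1) to 2.95 percentage points, and the mouse 3 difference from -16 (without mouse 3 tumor 2) to 59 SNVs. The number of passing lists hides changes of membership: by gene span 2 others passed, and without T>G calls or at a joint quality of at least 30 the 3 passing lists included the olfactory and vomeronasal receptors and not the long genes.

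The planned placement by coding length and the planned expected ratios of protein-altering to synonymous SNVs were not run. No paired analysis was possible because the tumors form 1 group and no 2 groups with files share replicate numbers. The labels number tumors within mice 2 and 3, and those tumors were compared within each mouse, but a tumor number names a tumor and is no condition shared across mice. Depth limits the lists: the lowest tumor depth at a call was 12 reads, and low-share changes at such sites would not be listed.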

Other observations

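All tests in this part were chosen after the data were seen.

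Olfactory and vomeronasal receptor genes, large families of chemosensory receptors with similar copies, make up 6.69% of protein-coding genes. Among distinct SNVs in protein-coding genes, pseudogenes left out, they held 23 of 126 outside the T>G class (18.3%, Wilson interval 12.5 to 25.9%) and 12 of 239 in the T>G class (5.02%, 2.90 to 8.57%). The difference between the classes passed Fisher's exact test (odds ratio 4.22, p = 0.000111), while the share of genes takes no account of gene length. Of the calls outside the T>G class, the mouse 3 tumors had 8 of 31 and 11 of 43 in these genes, mouse 1 tumor 1 had 1 of 27, and the mouse 2 tumors had 3 of 29 and 0 of 10. At all distinct SNVs outside the T>G class, receptor pseudogenes included, reads of the looser mapping tier added a median of 2.80% in receptor genes and 1.04% in other genes, with a mean difference of 8.39 percentage points (permutation p = 0.0131).

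The bases around changed T positions differed from those around unchanged T bases in the codons of coding SNVs changed at their first or last base. These unchanged bases were not matched to the changed sites by codon position. C preceded 26 of 37 T>C and T>A sites (70.3%, Wilson interval 54.2 to 82.5%) against 31.6% of unchanged T bases (Fisher's exact adjusted p = 0.000296 over 16 tests). C preceded 24.1% of T>G sites, which did not pass the same test (odds ratio 0.689, exact adjusted p = 0.240). C followed the changed T at 6.41% of T>G sites and 17.6% of T>C and T>A sites, against 45.8% of unchanged T bases (exact adjusted p = 3.01e-09 and 0.00837). T followed 61.8% of T>C and T>A sites and 47.4% of T>G sites, against 14.8% of unchanged T bases. Without matching by codon position, the sequence of codons around any T cannot be told apart as a cause for either set. The odds ratios for a following T were 9.14 (95% interval 3.74 to 23.3) at T>C and T>A sites and 5.15 (2.61 to 10.4) at T>G sites. The scarcity of C raises these values: with sites followed by C left out, the odds ratios were 7.82 (2.72 to 25.2) and 2.72 (1.32 to 5.74). Where both neighbors were known, 10 of 20 T>C and T>A sites and 11 of 42 T>G sites had C before and T after, a difference that did not pass Fisher's exact test (p = 0.0871). Unchanged T bases with both neighbors known were not counted, so an excess of that sequence over codons in general was not tested. T>G sites also had A before the changed T more often than unchanged bases did (39.2% against 18.9%, exact adjusted p = 0.00274), in 46.6% of those under a joint quality of 30 and 20.8% of those at 30 or above (Fisher's exact p = 0.00265), so the class may mix calls of different origin. T followed 12 of 13 T>G calls in mouse 3 tumor 1 and 6 of 23 in mouse 2 tumor 2, but the following base did not pass a test of differences over the 5 tumors (permutation p = 0.0626).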
